A study of Homo sapiens with 4 samples.

How the data were processed

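The series holds 4 two-colour Agilent arrays of A549 RNA, 2 for each of 2 biological replicates. On every array control RNA and MALAT-1 knockdown RNA were hybridised together, with the dyes swapped between the arrays of a replicate. Cells were transfected with SiMALAT2 in replicate 1 and with MALAT483 in replicate 2, per the labels' protocols. The labels state that these are biological replicates.

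Scanned images were turned into spot values with Agilent Feature Extraction 9.5 (9.5.3.1 in the headers), per the submitters' processing notes and the file headers. The deposited scanner files give, for each of 45015 spots, the mean intensity and the median intensity of the local background in each channel, on a linear scale and not normalized, per the file headers. They also hold a processed ratio on the log10 scale, Cy5 over Cy3, after the scanner software's background subtraction and dye normalization, per the file headers, and flags for spots well above background, saturated or non-uniform. The deposited value table of the series holds log10 ratios rounded to 2 decimals by the authors, with scale and direction not stated. Set against the scanner ratios over spots well above background, its columns correlated at -1.0 on arrays with knockdown RNA in Cy5 and at 1.0 on the others, so it holds control over knockdown on all 4 arrays, opposite to the direction used here. Column medians were 0.03, -0.04, 0.03 and -0.02, and no further centring was found. Probe coordinates are on build hg17, per the file headers.

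From the scanner files, limma 3.58.1 in R 4.3.3 corrected background with normexp (offset 50) and normalized each array by loess (span 0.3) with the 1639 control spots at weight 0. Control spots were then dropped, as were spots marked as non-uniform or population outliers in either channel, 286 to 844 per array. Repeat spots of a probe were averaged, and each log2 ratio was turned to knockdown over control. A probe was kept if the control RNA, or the knockdown RNA, was well above background on all 4 arrays, which left 24552 of 41000 probes. The kept probe with the highest mean intensity stood for a gene. Of the 4660 genes with more than 1 kept probe, 25 had probes that differed in sign and by more than 1 in log2 ratio. Gene names came from a RefSeq table of assembly GRCh38.p14, of which no coordinate was used. It named 23434 probes by accession, 2285 by symbol and 1028 by synonym, the last 2 only on the same chromosome. The other 14253 keep the file's name. In 2 scanner files 1 line ended in a lone carriage return and was split there.

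The dye-swapped arrays of a replicate share their RNA and were averaged, which leaves n = 2. For 833 genes a mean rests on fewer arrays because of an outlier spot. The model was an intercept fitted by lmFit and eBayes to the 2 replicate means, two-sided, with Benjamini-Hochberg adjustment over 18415 genes and a threshold of 0.05. It has 1 residual degree of freedom and 2.14 prior ones. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over 29 lists. At that preset it compares members with other genes, so its p does not measure the spread between the 2 replicates. An estimated correlation and fry stand beside it, the first of which has the same 1 residual degree of freedom. With that and 29 lists, camera with an estimated correlation could hardly reach the threshold, so a list that fails it is not thereby argued against. The steps were tested on simulated arrays with 200 changed genes. Each gene's spread was drawn from the SDs between the 2 real replicates, which include the difference between siRNAs. An SD of 2 values is imprecise, so some simulated genes may be noisier than any real one. In the simulation the median fitted log2 size was 0.91 for 2-fold and 1.92 for 4-fold genes. Of 100 unshifted lists of 30 genes, 3.0% had a camera p under 0.05. Simulated genes varied independently of each other, so this share does not cover real lists whose members vary together.

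Choices made before the data were examined were the fit, the filter, the lists and the rule for named genes. That rule takes the 15 highest and 15 lowest mean ratios among genes past the threshold with the same sign on all 4 arrays and a current symbol. Where fewer pass, it fills up with genes at least 2-fold different with both siRNAs and with the same sign on all 4 arrays, given as values and not as changes. Each described list adds up to 4 members with the largest ratios of 1 sign on all 4 arrays. MALAT1, NEAT1 and the 4 motility genes are always named. The siRNA comparison adds the 5 genes with the largest difference in each direction among those with opposite signs on both arrays of each siRNA. The lists on motility, cell cycle, stress, metabolism, RNA processing and cell-type markers are those named with their results.

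Alternatives were no background correction, normexp with offset 0, the scanner's log ratio, median centring, Aquantile scaling, no filter or a looser one, outlier spots kept, the mean of all probes of a gene and the series value table. Others were leaving out each replicate or array, models of 4 arrays with the slide as a random block or with none (both with a dye term), eBayes with trend and robust, an adjusted p of 0.10, a test without moderation, and 1.5-fold. The limma function for block correlations gave no value with a dye term on 4 arrays. It was therefore computed by the same formula from the sums of squares between and within slides (0.88; 0.50 by limma with no dye term). For 44 genes whose remaining arrays had a single dye orientation, the models of 4 arrays could fit no dye term, and these genes stayed in with the knockdown term alone. Lists under the block fit were tested with cameraPR. A search of 3' UTRs for seed sites was planned but not run, as no transcript sequences were used here. In its place the array probes were searched.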

Results

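RNA from A549 cells, an established human lung adenocarcinoma line, was compared after knockdown of MALAT-1 and in control cells. MALAT-1 (gene MALAT1) is a long non-coding RNA that stays in the nucleus and gathers in nuclear speckles. The series title places the comparison in a question about cell mobility, namely which messenger RNAs change when MALAT-1 is depleted. Total RNA of both conditions was hybridised together on 4 two-colour arrays of 60-base probes. There were 2 biological replicates, each hybridised with the dyes in both orientations, and each replicate used a different siRNA. Replicate 1 received SiMALAT2 (GATCCATAATCGGTTTCAA) and replicate 2 received MALAT483 (CACAGGGAAAGCGAGTGGTTGGTAA). The siRNA target sites were not placed on the genome here. The labels give the control cells only as control, with no duplex named, and do not say whether the 2 replicates had separate control cultures. Each siRNA was used in 1 replicate, on 1 slide and on 1 scan day, so siRNA, slide and replicate cannot be told apart. Median spot intensity lay between 157 and 319.5 in Cy3 and between 346 and 698 in Cy5, over local backgrounds of 37.0 to 44.0 and 69.0 to 70.5. The MALAT483 slide was the brighter, at 274 and 319.5 in Cy3 (164 and 157 with SiMALAT2) and 675 and 698 in Cy5 (364 and 346). It alone had saturated probe spots, 32 and 45 in Cy5. How far this bears on differences between the siRNAs was not tested. Between 58.9% and 82.8% of probe spots per array and channel were well above background. The number of arrays limits the precision of every value below. All ratios are knockdown over control, and each is the mean of 2 replicates unless the siRNA is named.

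MALAT1 itself was lower in the knockdown RNA on all 4 arrays. Its brightest probe, on chromosome 11 at 65026718 to 65026777 of hg17, had a log2 ratio of -2.05 with SiMALAT2 and -2.85 with MALAT483 (mean -2.45 ± 0.57, SD, n = 2). The RNA left was 24.2% of control with SiMALAT2 and 13.9% with MALAT483. In the limma fit of all genes its adjusted p was 0.456, above the threshold of 0.05. The other 3 MALAT1 probes had smaller ratios. The probe starting at 65025148 gave -1.36 and -2.07, that at 65029449 gave -1.32 and -1.46, and that at 65030385 gave -0.59 and -0.40. Knockdown RNA was well above background on only 2 of 4 arrays for the first and second of these. The mean over all 4 probes was -1.51. A probe that the array design names PRO1073 lies between MALAT1 probes, at 65025815 to 65025874, with its coordinates written in descending order. It had ratios of -1.06 and -1.31, with knockdown RNA well above background on 3 of 4 arrays, and was singled out after its values were seen. NEAT1, the neighbouring non-coding RNA that scaffolds paraspeckles, had ratios of opposite sign with the 2 siRNAs. Its brighter probe, at 64949850 to 64949909, had a log2 ratio of -1.02 with SiMALAT2 and 2.09 with MALAT483. The other NEAT1 probe gave -0.47 and 1.41. The 17 measured genes around the locus had a median log2 ratio of 0.08 (camera adjusted p = 0.834). Among those with the same sign on all 4 arrays, FRMD8 had 0.44 ± 0.29 and POLA2 had -0.44 ± 0.13.

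**Figure D1:**
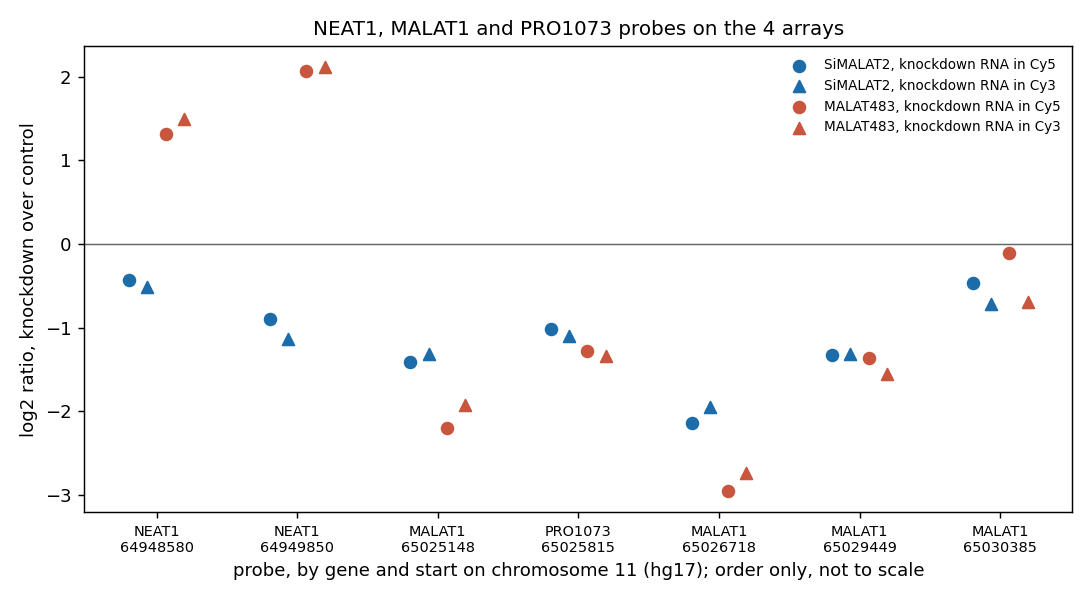
Log2 ratio of knockdown over control (vertical axis) for the probes of NEAT1, MALAT1 and PRO1073, ordered along chromosome 11 of hg17 (horizontal axis, not to scale), with 1 point per array, coloured by siRNA and shaped by the dye of the knockdown RNA. All MALAT1 points lie below 0, the lowest at -2.96, while the NEAT1 points lie below 0 with SiMALAT2 and above 0 with MALAT483.

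The next question was which genes changed with MALAT-1 depletion. MMP7, a matrix metalloproteinase, had a log2 ratio of 2.87 ± 0.18 (SD, n = 2), or 7.29-fold. HMOX1, the haem-degrading oxygenase, had 2.69 ± 0.58 and GPX2, a glutathione peroxidase, had 2.37 ± 0.34. CDH1, which encodes E-cadherin, had 2.06 ± 1.06. CNOT6, a deadenylase subunit of the CCR4-NOT complex, had -2.12 ± 0.20. These genes are given as values and not as changes, because limma called 0 of 18415 genes at an adjusted p of 0.05, and the lowest adjusted p was 0.456. With no adjustment, 1966 genes had a p under 0.05 (1190 higher and 776 lower), where 921 would be expected by chance. With the sign of replicate 2 turned, 398 genes had one. The same test without variance moderation found 0 genes after adjustment and 1261 before it. A fit that treated the 4 arrays as units, with the slide as a random block, called only MMP7 (adjusted p = 0.0395). A fit that took them as independent called 148 genes, but dye-swapped arrays of the same RNA are not independent. On simulated arrays with this design, whose spreads may exceed the real ones, the test called 0% of genes made 2-fold different and 0% of those made 4-fold different.

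A count by size alone was therefore set beside the test. With both siRNAs, 146 genes were at least 2-fold different in the same direction and had the same sign on all 4 arrays. Of these, 119 were higher and 27 were lower. At least 2-fold differences in opposite directions were seen for 33 genes. Independent lists of the sizes that each siRNA gave (372 and 673 higher, 186 and 435 lower) would share 13.6 higher and 4.39 lower genes. For opposite directions, independent lists of these sizes would also share fewer genes than the 33 seen. An overlap above independence is therefore not a measure of agreement alone. A control culture common to both replicates, which the labels leave open, would raise the overlap with no effect of the knockdown. In the simulation, 90.0% of 4-fold genes and 17.0% of 2-fold genes met this rule, as did 74 of 18185 unchanged genes. These values depend on the simulated spreads, so 74 is no estimate of chance passes among the real genes.

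Of the 15 genes with current symbols and the highest mean ratios among these 119, CEACAM6, a cell surface glycoprotein, came first. It had a log2 ratio of 3.31 ± 2.30, with 1.68 for SiMALAT2 and 4.94 for MALAT483. Its relative CEACAM1 had 2.11 ± 0.57, and FLRT3, a leucine-rich repeat membrane protein, had 2.83 ± 1.66. KCNJ16, an inwardly rectifying potassium channel, had 3.12 ± 0.71, with control RNA well above background on 2 of 4 arrays. SULF2, which removes sulfate from heparan sulfate chains, had 2.13 ± 0.71. Secreted proteins were INHBB, an inhibin and activin subunit (2.09 ± 0.16), and FGL1, a fibrinogen-like protein (2.03 ± 1.37). HLA-DMB, which helps load peptide onto MHC class II, had 2.12 ± 0.06. The other genes were CPLX2, a complexin of vesicle release (2.56 ± 0.44), ZNF469 (2.55 ± 0.55) and PRR15 (2.40 ± 0.86).

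Among the 27 lower genes, those with current symbols and the lowest ratios after MALAT1 and CNOT6 began with GAL, the neuropeptide galanin, at -2.06 ± 1.36. PTX3, a secreted pentraxin, had -1.69 ± 0.62, and RPS6KA5, a stress- and mitogen-activated kinase, had -1.67 ± 0.73. RRAD, a Ras-related GTPase, had -1.50 ± 0.23. SFRP1, a secreted Wnt antagonist, had -1.48 ± 0.51. LY6K (-1.38 ± 0.21), SLC26A2, a sulfate transporter (-1.36 ± 0.16, knockdown RNA well above background on 3 of 4 arrays), OTUB2, a deubiquitinase (-1.33 ± 0.18), and CLMP, an adhesion molecule (-1.28 ± 0.27), followed. FKBP11, a prolyl isomerase, had -1.21 ± 0.26. PEX19, needed for peroxisome membrane assembly, had -1.18 ± 0.17, but another of its probes differed from this in sign.

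**Figure D2:**
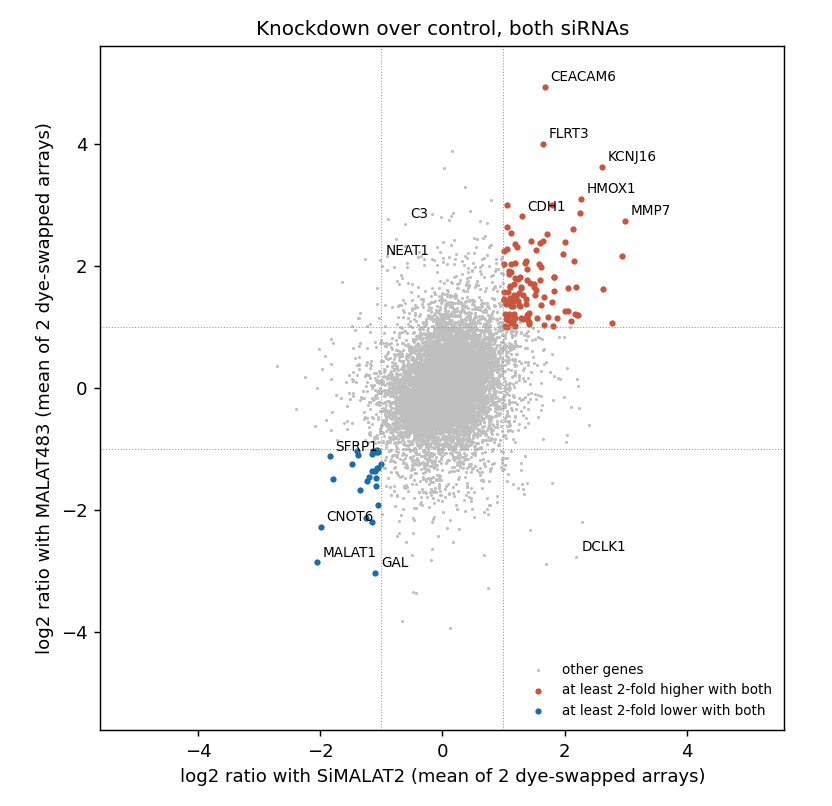
Log2 ratio of knockdown over control with SiMALAT2 (horizontal axis) against MALAT483 (vertical axis), 1 point per gene, each the mean of 2 dye-swapped arrays. Coloured points are the 119 genes at least 2-fold higher and the 27 at least 2-fold lower with both, and dotted lines mark 2-fold.

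Cell-cycle genes were lower as a group. The 38 measured G2/M and mitosis genes had a median log2 ratio of -0.61, with -0.70 for SiMALAT2 and -0.49 for MALAT483, and 36 of them were lower on all 4 arrays. HMMR, a hyaluronan-binding protein of the spindle, had -1.06 ± 0.30 (SD, n = 2). BIRC5, which encodes survivin, had -0.97 ± 0.32. CDC20, an activator of the anaphase-promoting complex, had -0.93 ± 0.05 and the checkpoint kinase BUB1 had -0.92 ± 0.12. The shift passed limma's camera test against all other genes (adjusted p = 3.57e-20; adjusted p = 0.696 with an estimated correlation of 0.20, against the preset 0.01). The smaller p compares genes with genes and does not measure the spread between the 2 replicates. The larger rests on 1 residual degree of freedom, so it could hardly have passed at any correlation. Over all genes 0 members passed, and adjusted over the list alone 25 of 38 did. The 34 genes of G1/S and DNA replication had a median of -0.41, with -0.44 for SiMALAT2 and -0.41 for MALAT483, and 21 were lower and 2 higher on all 4 arrays (adjusted p = 1.22e-09; adjusted p = 0.696 with an estimated correlation). The primase subunit PRIM1 had -0.88 ± 0.23, the ribonucleotide reductase subunit RRM2 had -0.82 ± 0.03 and the polymerase subunit POLE2 had -0.76 ± 0.18. Adjusted over the list alone, 0 of the 34 passed.

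p53 target genes were higher as a group. The 30 measured members had a median log2 ratio of 0.81, with 0.74 for SiMALAT2 and 0.86 for MALAT483. On all 4 arrays 24 were higher and 0 were lower. BTG2, an antiproliferative gene, had 1.93 ± 0.69, FDXR, a mitochondrial reductase, had 1.68 ± 0.12, the death receptor FAS had 1.46 ± 0.24 and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, had 1.32 ± 0.13. The adjusted p was 1.44e-15 in camera (adjusted p = 0.696 with an estimated correlation of -0.03). Over all genes 0 members passed, and adjusted over the list alone 13 of 30 did.

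Targets of NRF2, the transcription factor of the oxidative stress response, were also higher as a group. The median of 25 genes was 0.72, with 0.29 for SiMALAT2 and 0.98 for MALAT483, and 17 were higher and 1 lower on all 4 arrays. Beside HMOX1 and GPX2, the aldo-keto reductase AKR1B10 had 1.38 ± 0.87, saturated on 1 array, and the exporter ABCC3 had 1.19 ± 1.17. Camera gave an adjusted p of 1.53e-09 (adjusted p = 0.817 with an estimated correlation of 0.69), and 4 of 25 passed when adjusted over the list alone. The 24 autophagy and lysosome genes had a median of 0.31, with 0.25 for SiMALAT2 and 0.40 for MALAT483 (adjusted p = 0.0014; adjusted p = 0.696 with an estimated correlation), and 12 were higher and 3 lower on all 4 arrays. GABARAPL1 (1.41 ± 0.75), a homologue of yeast ATG8, the initiating kinase ULK1 (1.30 ± 0.05), WIPI1 (1.03 ± 0.89) and the lysosomal protein PSAP (0.68 ± 0.06) led them, and adjusted over the list alone 1 passed. The 30 genes of the unfolded protein and amino acid stress response had a median of 0.29, with 0.14 for SiMALAT2 and 0.39 for MALAT483 (adjusted p = 0.0014; adjusted p = 0.696 with an estimated correlation), and 12 were higher and 1 lower on all 4 arrays. The stress transcription factor ATF3 had 1.29 ± 0.14 and SESN2, which the p53 list also holds, had 0.87 ± 0.03. Adjusted over the list alone, 0 of the 30 passed.

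Epithelial junction genes were higher as a group, with a median of 0.52 over 17 genes (adjusted p = 0.028; adjusted p = 0.707 with an estimated correlation). Besides CDH1, the tight-junction protein CLDN2 had 1.03 ± 0.14, with control RNA well above background on 1 of 4 arrays. The keratin KRT19 had 1.03 ± 0.29 and the plakoglobin gene JUP had 0.65 ± 0.54. On all 4 arrays 6 were higher and 1 was lower, and the group median was 0.13 with SiMALAT2, within the range of matched random lists (-0.12 to 0.16), and 0.60 with MALAT483. Under 14 other processings and left-out arrays its adjusted p ranged from 0.0113 to 0.0547, and 12 of them kept it past the threshold. The median was 0.18 with no filter. TGF-beta and YAP target genes had a median of 0.32 over 19 genes (adjusted p = 0.0392; adjusted p = 0.755 with an estimated correlation), with 0.51 for SiMALAT2 and 0.05 for MALAT483. The latter lies within the range of matched random lists (-0.19 to 0.22). On all 4 arrays 6 were higher and 1 lower. COL1A1 (1.45 ± 0.41), a collagen chain, TGFB2 (0.99 ± 0.23) and PMEPA1 (0.89 ± 0.72) had positive ratios, and the receptor kinase AXL had -0.93 ± 0.33. Adjusted over the list alone, 0 genes passed in either list.

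Chaperone and splicing genes had slightly negative medians. The 21 heat shock and chaperonin genes had a median of -0.29, with -0.31 for SiMALAT2 and -0.23 for MALAT483 (adjusted p = 0.000137; adjusted p = 0.696 with an estimated correlation), and 10 were lower and 1 higher on all 4 arrays. Of those lower on all 4 arrays, the lowest were subunits of the cytosolic chaperonin, CCT4 (-1.13 ± 0.17), CCT5 (-0.65 ± 0.39), CCT7 (-0.41 ± 0.07) and CCT2 (-0.34 ± 0.20). The 30 SR protein and nuclear speckle genes had a median of -0.16, with -0.24 for SiMALAT2 and -0.09 for MALAT483 (adjusted p = 0.00169; adjusted p = 0.696 with an estimated correlation), and 9 were lower and 1 higher on all 4 arrays. Matched random lists reached from -0.13 to 0.16 with MALAT483, which includes its median, and 1 of its arrays had a median of 0.05. Under 14 other processings and left-out arrays the median over both siRNAs ran from -0.25 to -0.07. Of the genes lower on all 4 arrays, the splicing factors SRSF2 (-0.58 ± 0.35) and SRSF1 (-0.38 ± 0.08), the kinase CLK4 (-0.38 ± 0.02) and TRA2A (-0.37 ± 0.16) had the lowest ratios. Adjusted over the list alone, 0 genes passed in either list.

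The 4 motility genes recalled as followed up by the study were all lower on all 4 arrays. PTBP3, an RNA-binding protein, had -1.49 ± 0.61 (SD, n = 2). CTHRC1, a secreted collagen triple helix repeat protein, had -1.35 ± 0.82. CCT4 had -1.13 ± 0.17 and HMMR had -1.06 ± 0.30. Camera gave an adjusted p of 0.000104 (adjusted p = 0.696 with an estimated correlation), and 4 of 4 passed when adjusted over the list alone against 0 over all genes. These genes were picked on these same samples, so neither their direction, the camera result nor that count is independent evidence, and the list adds nothing to the other 10 called. HMMR is also in the G2/M and mitosis list and CCT4 in the heat shock and chaperonin list, where their values are likewise no independent evidence.

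**Figure D3:**
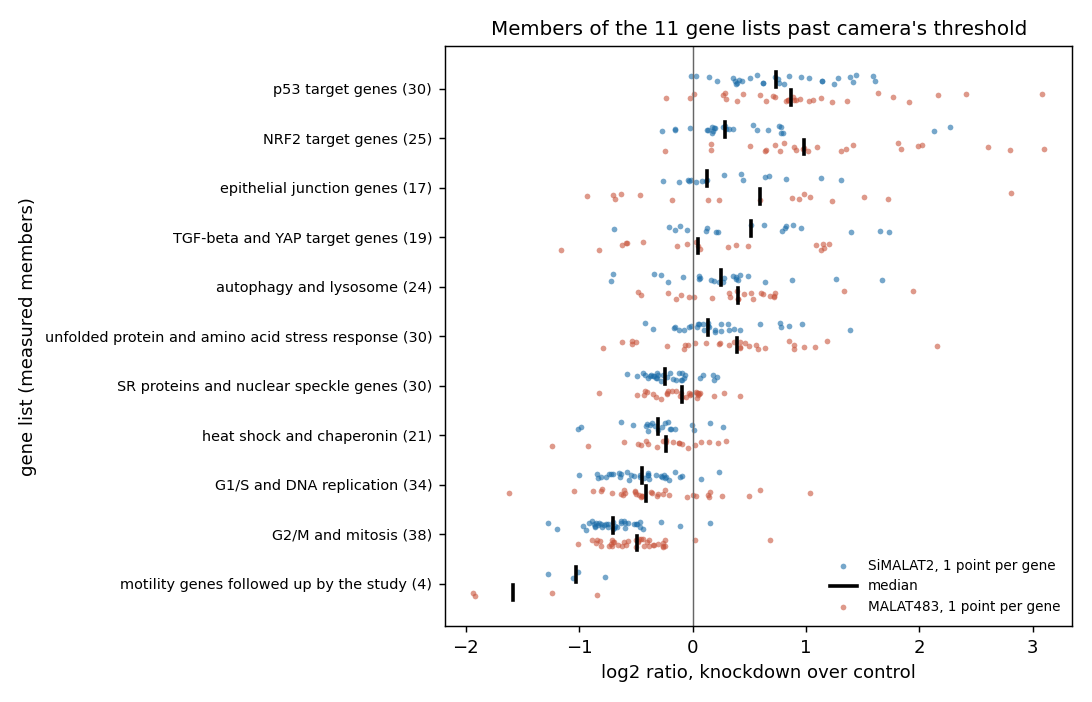
Log2 ratio of knockdown over control (horizontal axis) for each measured member of the 11 gene lists past camera's threshold (vertical axis, with the number of members), separately for each siRNA, with bars at the medians. Medians run from -1.58 for the motility genes to 0.98 for the NRF2 targets, both with MALAT483, and the motility genes were picked on these samples.

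For 18 of the 29 lists camera gave no call. Among motility-related lists, the 44 cell migration and cytoskeleton genes had a median of 0.10 (adjusted p = 0.372), the 14 integrins and adhesion receptors 0.23 (adjusted p = 0.149) and the 32 matrix and protease genes 0.14 (adjusted p = 0.125). The 17 mesenchymal transition genes had a median of -0.06 and a mean of 0.08 (adjusted p = 0.834). Within them ACTA2, a smooth-muscle actin, had 1.85 ± 0.29 and the repressor ZEB2 had -0.63 ± 0.15. The interferon response genes had a median of 0.10 over 26 members (adjusted p = 0.214), and the NF-kB and inflammatory cytokine genes -0.19 over 20 (adjusted p = 0.149). Metabolic lists had medians of 0.16 for cholesterol synthesis (adjusted p = 0.261), -0.00151 for fatty acid synthesis (adjusted p = 0.729), 0.01 for hypoxia and glycolysis (adjusted p = 0.834) and 0.09 for the respiratory chain (adjusted p = 0.183). The median was 0.02 for growth factors and EGFR ligands (adjusted p = 0.729, in the negative direction), 0.05 for the RNA interference machinery (adjusted p = 0.974), -0.04 for cytosolic ribosomal proteins (adjusted p = 0.65, but past the threshold under 3 of 14 alternatives, with medians from -0.18 to 0.08) and -0.02 for apoptosis regulators (adjusted p = 0.834). Ribosomal protein medians were positive with knockdown RNA in Cy5 (0.18 with SiMALAT2, 0.29 with MALAT483) and negative with it in Cy3 (-0.30 and -0.22). Marker lists gave 0.10 for lung epithelium (adjusted p = 0.247), 0.02 for leukocytes (adjusted p = 0.638) and 0.03 for fibroblasts and endothelium, of which 3 of 16 genes were measured (adjusted p = 0.368). Adjusted over the list alone, 7 matrix and protease genes, 1 mesenchymal transition gene and 1 fibroblast and endothelial gene passed. With an estimated correlation in camera, 0 of 29 lists passed (lowest p before adjustment 0.067), which 1 residual degree of freedom all but fixed in advance. In fry 0 passed after adjustment.

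The 2 siRNAs were then compared with each other. Across genes, which are not independent replicates, their log2 ratios had a Pearson r of 0.27 and a Spearman rho of 0.26, and 59.2% of genes had the same sign, which a shared control would also raise. The dye-swapped arrays of 1 siRNA correlated with an r of 0.83 each. Of 17582 genes measured on all 4 arrays, 6247 had the same sign on all 4. Genes with opposite signs that held on both arrays of each siRNA numbered 3654. Those most in favour of MALAT483 were KCNJ2, a potassium channel (-1.27 with SiMALAT2 and 2.12 with MALAT483, knockdown RNA well above background on 3 of 4 arrays), SLC1A3, a glutamate transporter (-1.65 and 1.74), the complement component C3 (-0.61 and 2.69), the repressor BCL6 (-0.76 and 2.44) and NEAT1. Those most in favour of SiMALAT2 were the kinase DCLK1 (2.19 and -2.76, knockdown RNA likewise on 3 of 4 arrays), the inflammasome sensor NLRP1 (1.70 and -2.87), the GTPase RAB39B (2.29 and -2.18), the ubiquitin ligase MARCHF4 (0.74 and -3.27) and the pentraxin NPTX1 (1.43 and -2.33). The difference between siRNAs has 1 replicate on each side and was not tested.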

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

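The tests of seed sites in probe sequences were chosen after their medians had been seen, including the comparison with other sequences of the same bases, whose ranks were not yet known.

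Several genes had ratios of opposite sign on the arrays of the 2 siRNAs, which differ in slide and culture too, and none of these differences was tested. For MALAT483 minus SiMALAT2, the difference in log2 ratio was 3.39 for KCNJ2, 3.39 for SLC1A3, 3.30 for C3, 3.20 for BCL6 and 3.11 for NEAT1. It was -4.95 for DCLK1 (knockdown RNA well above background on 3 of 4 arrays, as for KCNJ2), -4.57 for NLRP1, -4.48 for RAB39B, -4.01 for MARCHF4 and -3.76 for NPTX1. Medians of 6 gene lists had 1 sign on both arrays of SiMALAT2 and the other sign on both arrays of MALAT483, again untested. The differences were -0.55 for matrix and protease genes (0.43 with SiMALAT2 and -0.12 with MALAT483), -0.52 for mesenchymal transition genes, 0.48 for NF-kB and inflammatory cytokine genes, 0.57 for cholesterol synthesis genes, -0.078 for apoptosis regulators and -0.16 for lung epithelial markers. Another 5 lists had medians of opposite sign over the 2 arrays of each siRNA but not on every array, the widest apart being integrins and adhesion receptors (0.50 with SiMALAT2 and -0.10 with MALAT483).

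A candidate explanation for part of the difference is silencing of other transcripts through the seed of each siRNA, the guide bases 2 to 8, taking the printed sequence as the sense strand. The 53 kept probes that hold the MALAT483 site GTTGGTA had a median log2 ratio of -0.44 with MALAT483 and 0.06 with SiMALAT2 (central 95% of 10000 intensity-matched probe sets, -0.10 to 0.10), and 24.5% were at least 2-fold lower with MALAT483, against 2.37% of all kept probes. The 128 probes with the SiMALAT2 site GGTTTCA had -0.10 with SiMALAT2 (matched range -0.05 to 0.06) and 0.09 with MALAT483. Only 2.34% were at least 2-fold lower with SiMALAT2, against 0.96% of all kept probes. The median with MALAT483 is about as far from 0 and cannot come from the SiMALAT2 seed, so this shift is weak evidence. Among named genes only COL1A1 has a probe with this site, and its ratio with SiMALAT2 was 1.73. Base composition is argued against, since the MALAT483 site ranked lowest of 140 sequences of the same bases (0.714%) and the SiMALAT2 site ranked 8 of 371 (2.16%). How much of the opposite-sign differences seeds account for stays open, as does a slide or culture difference, since only 60 bases per transcript were searched and 0 of the opposite-sign genes named here, and 0 of the 26 genes other than MALAT1 at least 2-fold lower with both, had a site there.

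On the 4 arrays, the log2 ratios of ZNRD2 and COX7A2 each had 1 array far from the other 3, with gaps of 0.979 and 0.978 of the whole range, above Dixon's 95% critical value. ZNRD2 ran from -0.39 to -0.07 and COX7A2 from 0.10 to 0.50. These were 2 of the 135 named genes tested. Chance would mark about 1 in 20 if the 4 values were independent, which dye-swapped arrays are not. Many named genes were also picked for 1 sign on all 4 arrays, so that rate does not apply here.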

How the results depend on the processing

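The log2 ratio of MALAT1 stayed negative under every other processing, from -1.51 with the mean of all probes to -2.51 with the series value table. Its adjusted p ranged from 0.0494 to 0.505, and the lowest, at -2.45, came from taking the 4 arrays as independent. Without a replicate or an array its ratio lay between -2.85 and -2.05. The count of genes past the threshold was 0 under all alternatives except 1 gene with the slide as a random block, 148 with independent arrays and 1261 in the unmoderated test at an unadjusted p of 0.05. The last follows from leaving out the adjustment, and the second from counting dye swaps as replicates. Genes at least 2-fold different with both siRNAs numbered 257 with the scanner's log ratio, 252 with the series value table and 652 at 1.5-fold (449 higher, 203 lower, 216 opposite), against 146. The cause was not tested for the first 2, of which 145 genes each were among the 146. With normexp at offset 0 in place of 50 there were 209, which held all 146, so the offset alone moves this count. Without 1 array there were 144 to 148 genes. Without replicate 1 or 2, where the rule rests on the other siRNA alone, there were 1107 and 558. The correlation of the 2 siRNAs ranged from 0.25 to 0.29. The number of lists past camera's threshold was 9 to 13 of 29, and 0 with an estimated correlation and 0 in fry, which have 1 residual degree of freedom. Of 135 named genes, the mean of SLC1A3 alone changed sign under another scaling, from 0.05 to -0.11 with the scanner's log ratio. No list reversed among those called, while medians of some uncalled lists near 0 changed sign. Calls were gained by the ribosomal protein list (lowest adjusted p 0.00264, with median centring or without 1 of 2 arrays), by the matrix list with no filter and under the block, and by the NF-kB and respiratory chain lists with no filter. The ribosomal medians changed sign with the dye of the knockdown RNA, and without 1 array a replicate rests on a single dye. Ribosomal calls without an array therefore cannot be read as an effect of the knockdown. The epithelial junction list lost its call under both other filters and, like the TGF-beta list, with independent arrays. No call count exists without a replicate, and no correlation of siRNAs. The 2 conditions share each array, so the ratio is already the pair and no separate paired analysis was run.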

Other observations

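The tests of matched lists and of the interferon genes were chosen after the list medians had been seen, and those of brightness and scaling before, though how far the scalings move the centre was looked at afterwards.

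Within lists that camera did not call, single members had large ratios of the same sign on all 4 arrays, given as values (mean of 2 replicates ± SD). Among inflammatory genes the cytokine IL11 had -1.90 ± 2.02, CXCL8, which encodes interleukin 8, had -1.53 ± 0.76 and IL6 had -0.71 ± 0.05 (knockdown RNA well above background on 3 of 4 arrays), while PTGS2, a prostaglandin synthase, had 1.19 ± 1.24. Growth factor genes went both ways, with 7 higher and 10 lower on all 4 arrays of 30. FGFBP1 (1.71 ± 0.49) and IGFBP3 (1.38 ± 0.39) had positive ratios, and FGF2 (-0.95 ± 0.33) and the EGFR ligand EREG (-0.94 ± 0.03) had negative ones. The glucose transporters SLC2A1 (1.42 ± 0.65) and SLC2A3 (0.91 ± 0.37) had positive ratios, and ANGPTL4 (-1.12 ± 0.72) and the hexokinase HK2 (-0.94 ± 0.82) negative ones. Among adhesion genes, EPCAM had 0.84 ± 0.10 and MCAM had -1.25 ± 0.73, and the protease MMP9 had -0.43 with SiMALAT2 and -3.36 with MALAT483.

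The joint shift of mitosis genes (lower) and p53 targets (higher) with both siRNAs was set against 2 technical explanations. All 4 medians (2 lists, 2 siRNAs) lay outside the central 95% of 10000 lists matched on intensity and probe GC content, which argues against either as the source. Interferon response genes lay below the p53 targets by at least 0.55, more than the SD of the interferon genes with that siRNA (0.32). Both lists' medians were known when this rule was chosen, so it does not decide whether an interferon response is the source. The interferon medians of 0.19 with SiMALAT2 and 0.04 with MALAT483 were at the 99.6th and 76.9th percentiles of matched lists. A test by percentile, considered first, would thus have kept a small response to SiMALAT2 open. Open are also loss of MALAT-1 itself, which no rescue tests here, transfection if the controls received none, and targets shared by the 2 duplexes. A control culture common to both replicates, which the labels leave open, could give a joint shift too, and these may act together.

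More genes were at least 2-fold higher than lower with both siRNAs (81.5% of 146). A signal floor could hold back falling genes, but among the brightest 4604 genes 77.8% were higher (21 against 6, exact 95% interval 57.7% to 91.4%), too few to exclude it. At least 79.4% were higher under 4 other processings, but these left the median of all genes between -0.025 and 0.0013, so a wrong centre stays open too. With each siRNA alone, 66.7% (SiMALAT2) and 60.7% (MALAT483) of genes at least 2-fold different were higher. Whether the excess is biological stays untested.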
